A study of Homo sapiens with 3 samples.

How the data were processed

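Total RNA of MHCC-97H cells was labelled with Cy3 and hybridised to Agilent one-colour arrays, 2 for cells with an shRNA against UGT2B15 and 1 for cells with a control shRNA, per the labels. All 3 arrays sat on the same slide, so slide does not separate the groups. Per the file headers, Agilent Feature Extraction 10.7.1.1 read the scans, and the submitters' processing notes name Agilent Feature Extraction 10.7 and limma without saying what limma was used for. The processed signal is an intensity from which, per the file headers, the software had subtracted a spatially detrended background and which it had divided by a multiplicative surface, with a surrogate in place of signals not above background. It was not normalized between arrays. The mean signal of a spot and its local background are intensities without correction, per the file headers, and the flags for spots well above background and for outliers were taken as the scanner files give them. The deposited value table holds log2 values. Set against the scanner files, each of its columns had a rank correlation of 0.9999 with its own array, its medians were 4.00, 4.00 and 3.99, and its values differed by a median of 0.001 from quantile-normalized log2 processed signals, which settles its scale and direction and shows no centring of genes. It served as an alternative.

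Each array held 62976 spots, of which 60901 were not controls. The 75th percentile of the processed signal was 181 and 160 on the shRNA arrays and 154 on the control array, and the lowest signal called well above background was 16.0, 16.5 and 16.7. No spot was saturated, and 106, 149 and 101 spots carried an outlier flag. Control spots and flagged spots were left out, spots of the same probe were averaged, and values were log2 of the processed signal minus the 75th percentile of the array. This left 4 probes untested because of flags. Probe names come from the files, updated by RefSeq accession, symbol or synonym through a table of human genes: of 58201 probes, 34966 have a current symbol (31104 by accession, 3366 by symbol and 496 by synonym), 21728 carry only the name in the file and 1507 have no name. Probe positions are those of the files, on hg19.

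A feature was a gene, represented by its probe with the highest mean signal, or a probe without a gene name. Features well above background on both shRNA arrays or on the control were tested, 22107 in all, of which 15885 have a symbol. The test was limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread came from the shRNA arrays alone, with 1 residual degree of freedom and 3.54 prior degrees of freedom, and the control array was assumed to vary like them. A probe not well above background on any array of a group has only a bound there. Its fold is then written as at least N-fold, from the bright group's mean log2 value to the dim group's mean of, per array, the higher of the lowest signal called well above background and the probe's own. A p-value beside such a bound belongs to the fitted log2 difference, which uses the dim signals as they stand. It does not test the bound, and where both shRNA arrays are dim its spread is that of dim signals.

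Before the data were examined, 27 gene lists, the tests, most alternatives and the rule for named genes were fixed. The lists are those the results name. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation, on ranks and with fry, which asks whether a list moves one way without comparing it with other genes. The rule took UGT2B15 and its measured UGT2B paralogs, the 12 higher and the 12 lower genes past the threshold with the largest smaller-of-2 difference from control, up to 4 members of each list described by the same ranking plus those past the threshold, and GAPDH and ACTB. Where under 12 passed, places were to be filled by the same ranking without the threshold among genes measured on all 3 arrays, which was not needed. Only features with 1 gene symbol are named under it. Some genes that the rule or the later ranking picked are not reported here. Further genes measured on all 3 arrays, 5 further gene lists, cyclic loess normalization and the restriction to rows 193 to 384 of the array were added after the data were seen.

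The steps were tested on simulated data. Arrays for the 22107 features were drawn from their means and the prior spread, and 200 features were changed by known folds. For the comparison of UGT2B15 shRNA with control, limma called 0 of 50 features changed 2-fold, 1 of 50 changed 4-fold, 30 of 50 changed 8-fold and 45 of 50 changed 16-fold, and it called 6 unchanged features. With no feature changed it called 0. A list shifted by 0.40 (log2) had a camera adjusted p of 7.95e-08 with the preset correlation and of 0.997 with an estimated correlation. So the estimated correlation gave no call to a real shift of that size in this simulation. The features were drawn independently of each other, so the simulation cannot show how the preset correlation behaves where genes of a list move together.

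Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the deposited value table, stricter and no filters on dim probes, the mean of a gene's probes, an intensity trend or robust fit in eBayes, testing each probe or only features with a symbol, other thresholds, other list tests, and leaving out each shRNA array. With the intensity trend and the robust fit, lists were tested with cameraPR, the form of camera that takes the t values of a fit. List results of these settings therefore change the list test as well as the fit. The number of arrays and the signal over background limit the precision.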

Results

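Gene expression was measured with Agilent one-colour arrays in MHCC-97H cells, a human hepatocellular carcinoma line with a high capacity to metastasise. The cells carried a short hairpin RNA (shRNA), a transcript that is processed into a small RNA that silences a chosen gene. RNA was taken at day 7. In this set, 2 arrays came from cells with an shRNA against UGT2B15 and 1 array came from cells with a control shRNA. UGT2B15 is a UDP-glucuronosyltransferase, an enzyme that attaches glucuronic acid to androgens and to drugs. The comparison asks which transcripts differ between cells given the UGT2B15 shRNA and control cells. The labels number the UGT2B15 shRNA arrays but do not say whether they stand for different hairpins or for separate cultures, so p-values measure only the spread between these 2 arrays, which may be technical. The control has no replicate, and the tests assume that it varies like the shRNA arrays. Of 60901 spots that are not controls, 31139 (51.1%) and 30407 (49.9%) were well above background on shRNA replicates 1 and 2, and 30030 (49.3%) on the control array. The number of arrays limits the precision of every value.

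UGT2B15 gave a signal of 61.5 intensity units on the control array and 13.2 and 4.28 units on shRNA replicates 1 and 2. The control signal was well above background and neither shRNA signal was, so the probe's signal was at least 4.19-fold lower on the shRNA arrays. On the scale of log2 signal minus the 75th percentile of the array, UGT2B15 stood at -1.32 in the control and at -4.50 ± 1.02 (SD, n = 2) in the shRNA cells. The fitted log2 difference was -3.18 (SE 0.63) and did not pass the limma test over all features (Benjamini-Hochberg adjusted p = 0.186). Leaving out one shRNA array at a time gave -3.90 and -2.46. The single UGT2B15 probe lies on chromosome 4 of hg19 between 69512758 and 69512817 on the minus strand, and reads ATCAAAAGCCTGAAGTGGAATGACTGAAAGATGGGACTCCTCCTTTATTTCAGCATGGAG. The array's annotation also matches it to UGT2B17, so transcripts of both genes cannot be told apart.

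Probes named for neighbouring enzymes of the family differed from control by less than their standard error. UGT2B10 had a log2 difference of -0.11 (SE 0.23, limma adjusted p = 0.945), UGT2B11 of -0.07 (SE 0.23, limma adjusted p = 0.966) and UGT2B7 of -0.18 (SE 0.28, limma adjusted p = 0.922), and a second UGT2B7 probe gave 0.16. The annotation also matches the UGT2B10 probe to UGT2B11 and the UGT2B11 probe to UGT2B28, so these values are not of single genes. The UGT2B4 probe and the probe named for UGT2B28 alone were not well above background on any array. Among reference genes, GAPDH had a log2 difference of 0.26 (SE 0.23, limma adjusted p = 0.849) and ACTB of 0.08 (SE 0.24, limma adjusted p = 0.961). ACTB turned to -0.05 with the mean of its probes and to -0.18 with its probe in rows 193 to 384.

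**Figure D1:**
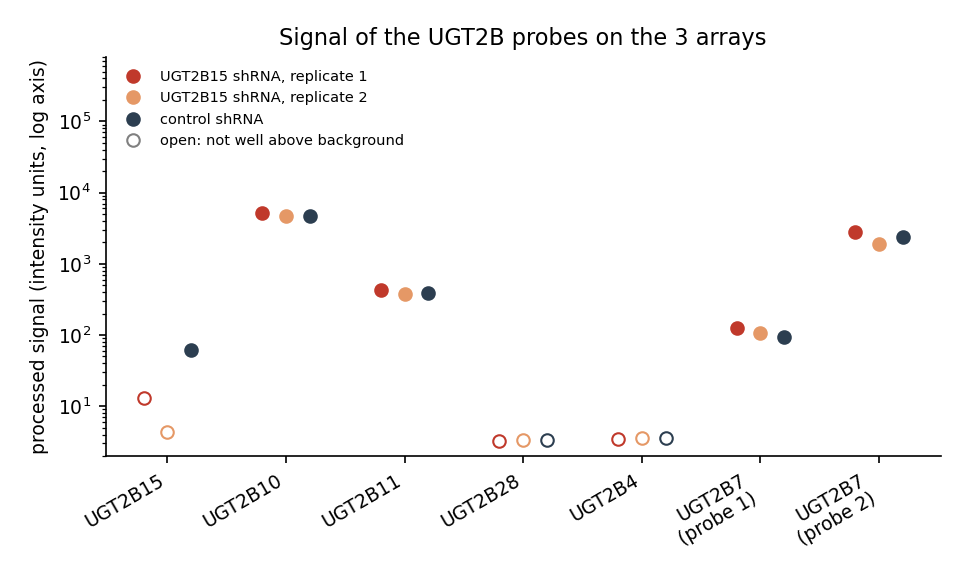
Processed signal (intensity units, log axis) of each UGT2B probe on the 3 arrays, 1 point per array, with open points for signals not well above background. UGT2B15 stands at 61.5 on the control array against 13.2 and 4.28 on the shRNA arrays, while the 3 points of UGT2B10, UGT2B11 and each UGT2B7 probe lie close together.

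IL6, the gene of the inflammatory cytokine interleukin 6, rose in the UGT2B15 shRNA cells by 2.37 on the log2 scale (SE 0.23, 5.15-fold, limma adjusted p = 0.0258). It was well above background on all 3 arrays, with differences from control of 2.33 and 2.40 on shRNA replicates 1 and 2. Its difference was 1.14 with normexp. The difference stayed at 2.37 when only features measured on all 3 arrays were tested, but limma did not call it (adjusted p = 0.37). In rows 193 to 384 it was also 2.37 and not called (limma adjusted p = 0.0739). The call of IL6 therefore depended on the set of features tested. Of the 303 features called in the main test, 273 were well above background on the control array alone. They enter the same Benjamini-Hochberg adjustment, and how far the IL6 call rests on them alone was not tested. TRIML2, of the tripartite motif family, rose at least 11.3-fold (limma adjusted p = 0.0158), but was not called in rows 193 to 384 (limma adjusted p = 0.0552). ARG1, the urea cycle enzyme arginase and a hepatocyte marker, rose at least 2.93-fold (adjusted p = 0.026). A second ARG1 probe stood 1.97 and 2.62 above control. It was the only 1 of 6 other probes of the 24 features called higher and dim on the control that was 2-fold higher, and the others, among them 2 of AFF2, were not well above background on any array. Nor was a second IL6 probe (-0.06). RRAD, a small GTPase of muscle, rose at least 2.46-fold (adjusted p = 0.0197). The other named genes that rose were KRTAP10-2, a hair keratin-associated protein, the receptor gene NOTCH4, AFF2, UCN2 (the peptide hormone urocortin 2), C2CD4A, TENT5C, CLDN22 (a claudin) and GALNT16, with lower bounds from 1.22-fold for C2CD4A to 1.92-fold for NOTCH4. Each of these, and TRIML2, ARG1 and RRAD, was well above background on both shRNA arrays and not on the control, so only a bound can be given. Their adjusted p belongs to the fitted difference and does not test the bound. Of these 11 genes, 5 still passed with quantile normalization and with the deposited table, and TRIML2 alone with normexp or an intensity trend. In rows 193 to 384, 7 of them were tested and 0 passed. The olfactory receptor gene OR6K2 rose by 2.28 (SE 0.25, limma adjusted p = 0.0383) and was measured on all 3 arrays. However, it passed in only 4 of 11 alternatives, not among them the test of features measured on all 3 arrays. Its difference was 0.97 with normexp. It was named after its value was seen, as was the long noncoding RNA LINC01349, which fell by 2.75 (SE 0.31, adjusted p = 0.0376) on the log2 scale and was also measured on all 3 arrays. LINC01349 passed in 6 of 10 alternatives, and its other probes (-2.12 and -0.16) were not well above background on any array.

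The 12 lower genes that the rule named had no signal well above background on either shRNA array. Their p-values belong to the fitted log2 differences, which use these dim signals (-4.87 for LINC02015), and do not test the bounds given here. MMP27, a matrix metalloproteinase, was at least 10.6-fold lower than on the control array (limma adjusted p = 0.0225), and LINC02015, a long noncoding RNA, at least 7.32-fold lower (limma adjusted p = 0.0158). NMRK2, a nicotinamide riboside kinase, was at least 6.15-fold lower, SLITRK2, a neuronal membrane protein, at least 6.44-fold, C1QC, a chain of complement C1q, at least 5.29-fold, and HTR1A, a serotonin receptor, at least 4.27-fold. LOC101927664, SNORD115-2, MRGPRG-AS1, GPR148, DNAJB7 and LINC00880 made up the rest, with bounds from 4.52-fold for GPR148 to 5.90-fold for MRGPRG-AS1. All 12 had spots in rows 1 to 192 of the 384 rows of the array, and 8 had a spot bright on the control array alone among their 6 nearest spots. Another probe of LINC00880 differed from control by 2.06 on shRNA replicate 1 and by -0.03 on replicate 2. For these genes the arrays hold a bright control spot, and 128 other probes of 93 of the genes called lower on the control alone included 1 that was likewise 2-fold lower and 119 that were dim on every array.

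In all, limma called 303 of 22107 features between UGT2B15 shRNA and control cells, 27 higher and 276 lower, and 115 of them carried a gene symbol. Of the 276 lower features, 273 were well above background on the control array alone, and 95.6% of those 273 lay in rows 1 to 192. Of the 27 higher features, 24 were well above background on both shRNA arrays and not on the control. Only 6 called features were measured on all 3 arrays: IL6, OR6K2 and the long noncoding transcript lnc-GPR137C-1 higher, and LINC01349, lnc-GRAMD2-1 and a feature known by a transcript identifier lower. Limma called 0 features when only those measured on all 3 arrays were tested (1504 at an unadjusted p under 0.05) and 0 in rows 193 to 384 (1072 at an unadjusted p under 0.05).

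**Figure D2:**
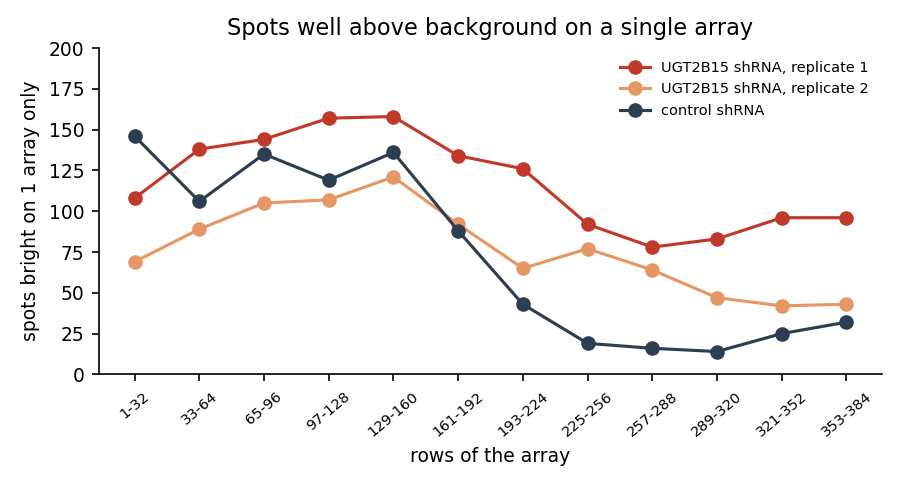
Number of spots well above background on 1 array alone, in bands of 32 rows from the top of the array, with 1 line per array. The control array had 146 such spots in rows 1 to 32 and 14 in rows 289 to 320.

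A count by size gave 910 features at least 2-fold from control in the same direction on both shRNA arrays, 292 higher and 618 lower, and 875 features at least 2-fold apart between the shRNA arrays themselves. The 875 rest on a single difference and the 910 on 2. With shRNA replicate 1 and then replicate 2 set against the other arrays, and the filter moved along, the count like the 910 was 697 and 690. Restricted to features measured on all 3 arrays, the count for the real grouping was 245, with 134 higher and 111 lower. It was 142 and 110 with shRNA replicate 1 and replicate 2 set apart. The genes named here were ranked by the smaller of their 2 differences among genes measured on all 3 arrays, a ranking added after the data were seen. Next to IL6 and OR6K2, the higher ones were HPD, an enzyme of tyrosine breakdown (log2 difference 2.88, SE 0.74, limma adjusted p = 0.306), APOA4, an apolipoprotein (2.42, SE 0.51, limma adjusted p = 0.212), PART1, VWCE, ARC (an activity-regulated gene of neurons), SLCO2B1 (an organic anion transporter), NPR3, MCAM (a cell adhesion molecule), PLAT (tissue plasminogen activator) and SPANXB1, with log2 differences from 1.60 for SLCO2B1 to 2.88 for HPD. A second VWCE probe measured on all 3 arrays gave 0.22 against 1.76 for the chosen probe.

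Next to LINC01349, the lower genes of this ranking were led by TFF2, a secreted trefoil peptide of gastric mucus, at -2.38 (SE 0.30, limma adjusted p = 0.0534), which passed in 5 of 11 alternatives. CEACAM5, the carcinoembryonic antigen, stood at -1.79 (SE 0.24, adjusted p = 0.065), CDH1, the epithelial adhesion molecule E-cadherin, at -1.80 (SE 0.24, adjusted p = 0.0692), and the hedgehog ligand IHH at -1.78 (SE 0.23, adjusted p = 0.0613). KNG1, the plasma protein kininogen, stood at -1.99 (-1.15 with normexp). The alcohol dehydrogenases ADH1C and ADH1A stood at -1.71 and -1.61, LINC01133 at -1.77 and TMEM14EP at -1.80. Over the alternatives ADH1A ranged from -1.62 to -1 and TMEM14EP from -1.81 to -0.89. SLC14A1, a urea transporter, stood at -1.57 with its brightest probe, but its other probes went the other way and the mean of its probes gave 0.02.

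**Figure D3:**
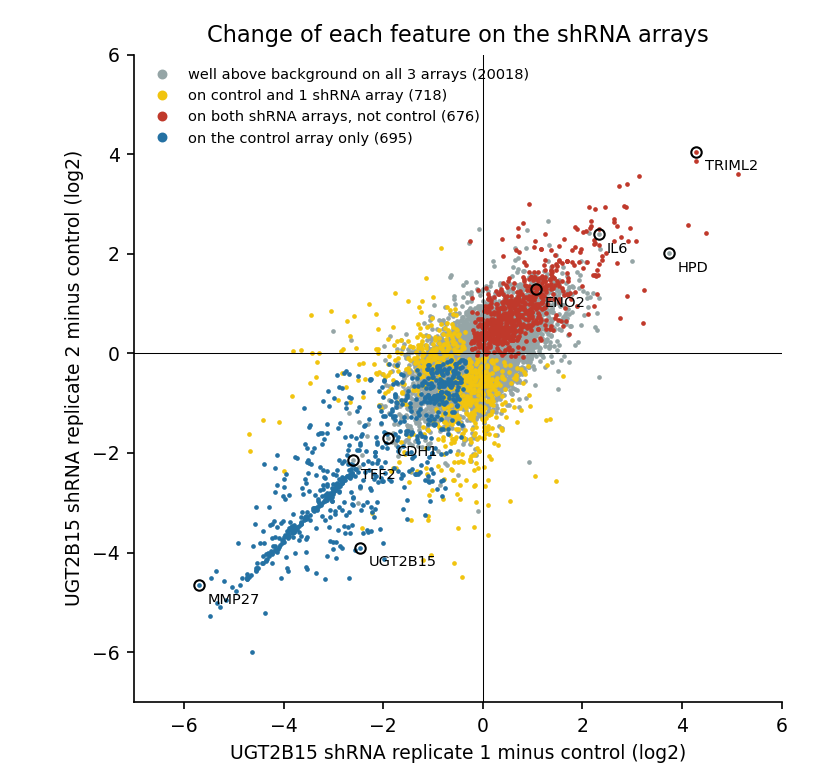
Difference of each of the 22107 tested features from the control array on shRNA replicate 1 (x axis, log2) and on replicate 2 (y axis, log2), coloured by the arrays on which it was well above background, with 8 genes circled. The 695 features bright on the control alone make up the lower left arm, and the 20018 features measured on all 3 arrays sit around 0.

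Genes of glycolysis and of the response to low oxygen were higher as a group on the 2 shRNA arrays than on the 1 control array. Of 31 measured members of the list, 25 were higher than control on both shRNA arrays and 1 was lower, with a median log2 difference of 0.40 (0.43 and 0.42 on replicates 1 and 2; limma camera adjusted p = 1.1e-06, and adjusted p = 0.881 with an estimated correlation). ENO2, a form of the glycolytic enzyme enolase, stood at 1.19 (SE 0.25), the glucose transporter SLC2A3 at 1.25 (SE 0.34; 0.36 with normexp), ANKRD37 at 1.16 (SE 0.23) and the vasodilator peptide ADM at 1.01 (SE 0.23). None of the 31 passed on its own, also adjusted over the list alone. With shRNA replicate 1 and then replicate 2 set against the other arrays, the median was -0.30 and -0.17.

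Cell cycle genes also rose as a group, with 35 of 43 members higher on both arrays, 3 lower and a median of 0.26 (0.23 and 0.33 on replicates 1 and 2; camera adjusted p = 0.000211, and adjusted p = 0.881 with an estimated correlation). With shRNA replicate 2 set against the other arrays, the median was -0.27, as far from 0. MCM6, part of the replicative helicase, stood at 0.91, the topoisomerase TOP2A at 0.75, cyclin A2 (CCNA2) at 0.70 and CDK1 at 0.54. Heat shock proteins had a median of 0.37, with 14 of 18 higher on both arrays (camera adjusted p = 0.00271, adjusted p = 0.881 with an estimated correlation, and 0.0718 with robust eBayes). Among these chaperones, HSPB8 stood at 0.83, CRYAB at 0.73, HSPB1 at 0.57 and DNAJB1 at 0.56. Immediate early genes, which respond first to growth signals, had a median of 0.21, with 13 of 22 higher and 2 lower on both arrays (camera adjusted p = 0.0262, adjusted p = 0.881 with an estimated correlation, 0.117 without a filter and 0.198 with robust eBayes). EGR2 stood at 0.93, JUNB at 0.75 and DUSP5 at 0.60, while DUSP2 stood at -0.71. No member of these 3 lists passed on its own, also adjusted over the list alone. List values given with robust eBayes, here and below, also rest on another form of camera, so they do not show the effect of the fit alone.

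Genes of epithelial-mesenchymal transition and invasion rose as a list, with 14 of 28 members higher and 3 lower on both arrays and a median of 0.21 (camera adjusted p = 0.0262, adjusted p = 0.881 with an estimated correlation, 0.0527 without a filter and 0.198 with robust eBayes). The median was 0.20 and 0.32 on replicates 1 and 2. With shRNA replicate 2 set against the other arrays the median was -0.24, further from 0. The matrix genes LOX, which cross-links collagen, and TGFBI stood at 1.45 (SE 0.24) and 1.39 (SE 0.24). E-cadherin (CDH1), an epithelial gene on this list, stood at -1.80. TWIST1, a transcription factor of mesenchymal cells, fell (at least 1.5-fold lower, adjusted p = 0.0318), and it was well above background on the control array alone. The TWIST1 call ended with normexp (-0.43, adjusted p = 0.496) and with an intensity trend (adjusted p = 0.194), and 3 other TWIST1 probes (-0.19, -0.16 and 0.21) were not well above background on any array. Adjusted over the list alone, 6 members passed, 4 higher and 2 lower (CDH1 and TWIST1), against TWIST1 alone over all features. Fibroblast markers, which share collagen genes with this list, had a median of 0.07 over 8 members (camera adjusted p = 0.099), and 3 of them passed adjusted over the list alone.

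2 lists fell. Ribosomal protein genes had a median of -0.20, with 35 of 39 lower and 1 higher on both arrays and medians of -0.25 and -0.11 on replicates 1 and 2 (camera adjusted p = 0.022, and adjusted p = 0.933 with an estimated correlation), and RPL13A stood at -0.44, RPS27 at -0.41, RPLP1 at -0.38 and RPL23 at -0.35. With shRNA replicate 1 set against the other arrays the median was 0.16. The median of the real grouping was -0.06 with quantile normalization (adjusted p = 0.434) and -0.08 in the deposited value table (adjusted p = 0.287), and the call also ended without a filter (adjusted p = 0.277) and with robust eBayes (adjusted p = 0.344). Genes of drug and xenobiotic metabolism had a median of -0.21, with 16 of 28 lower and 4 higher on both arrays (camera adjusted p = 0.0262, and adjusted p = 0.881 with an estimated correlation). The cytochromes P450 CYP2B6 and CYP1B1 stood at -1.48 (SE 0.26) and -1.39 (SE 0.26), the glutathione transferase GSTA2 at -0.86 and the monooxygenase FMO5 at -0.89. No member of either list passed on its own, also adjusted over the list alone. With shRNA replicate 2 set against the other arrays the median was 0.20, nearly as far from 0. The call of this list ended with the mean of probes (adjusted p = 0.0534), without a filter (adjusted p = 0.216) and with robust eBayes (adjusted p = 0.198). A second CYP1B1 probe gave -1.23 and a second CYP2B6 probe -0.23.

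The lists closest to the function of UGT2B15 did not pass. UDP-glucuronosyltransferases and their substrate supply had a median of -0.13 over 9 members (camera adjusted p = 0.45), with UGDH, which makes UDP-glucuronic acid, at 0.15. A probe named for UGT1A8, which also matches UGT1A1, UGT1A4 and UGT1A5, stood at -0.19. Steroid hormone metabolism had a median of 0.04 over 23 members (adjusted p = 0.45), and none of its members passed over all features. HSD17B6, STS and HSD11B1, not well above background on the control, had lower bounds of 2.58-fold, 1.61-fold and 1.38-fold (limma adjusted p = 0.106, 0.508 and 0.619; HSD11B1 turned to -0.01 with normexp), and HSD11B2 stood at -0.47. Androgen response genes had a median of 0.09 over 31 members (adjusted p = 0.467), with 15 higher and 11 lower on both arrays, and FKBP5 stood at 0.77, MAF at 0.66 and NDRG1 at 0.53. Among hepatocyte markers (median -0.15, 23 members, adjusted p = 0.743), ARG1 rose as given above and albumin (ALB) stood at -1.39, FGA at -0.71 and FOXA3 at 0.69. NF-kB target genes and inflammatory cytokines had a median of 0.14 over 20 members (-0.06 and 0.53 on replicates 1 and 2; adjusted p = 0.191). This list passed in 5 of 14 alternatives, among them normexp (adjusted p = 0.0115) and features measured on all 3 arrays (adjusted p = 0.0109), and its median was 0.70 in rows 193 to 384 (adjusted p = 0.0477). Of these IL6 rose, and CSF2, bright on the control array alone, fell (at least 1.34-fold lower, adjusted p = 0.0251), a call that ended with normexp (-0.52, adjusted p = 0.367) and with an intensity trend (adjusted p = 0.208). CCL20 stood at 1.98 and ICAM1 at 0.93. In the Hippo-YAP list (median 0.11, 22 members, adjusted p = 0.467), CRIM1, also bright on the control alone, fell (at least 1.84-fold lower, adjusted p = 0.0488), a call kept in 3 of 9 alternatives. Adjusted over each list alone, 2 NF-kB genes passed, 1 gene each in the hepatocyte, Hippo-YAP, steroid hormone and UDP-glucuronosyltransferase lists, and 0 androgen response genes. The 1 in the UDP-glucuronosyltransferase list was UGT2B15 itself, which was lower.

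The remaining lists did not pass either, and none of their members passed over all features; adjusted over the list alone, 2 fatty acid genes and 1 bile acid gene passed. Their medians were 0.13 for NRF2 targets and oxidative stress (camera adjusted p = 0.318), 0.12 for cholesterol synthesis and uptake (adjusted p = 0.467), -0.12 for fatty acid synthesis and oxidation (adjusted p = 0.34), -0.12 for bile acid metabolism and transport (adjusted p = 0.153), -0.10 for the unfolded protein response and amino acid stress (adjusted p = 0.34), 0.11 for interferon-stimulated genes (adjusted p = 0.418), -0.04 for p53 targets (adjusted p = 0.85) and -0.07 for apoptosis regulators (adjusted p = 0.902). The medians were 0.12 for fetal liver, progenitor and liver cancer markers (adjusted p = 0.85), 0.02 for Wnt and Notch targets (adjusted p = 0.887), 0.08 for the small interfering RNA machinery (adjusted p = 0.85), 0.42 for 7 endothelial markers (0.05 and 0.40 on replicates 1 and 2; adjusted p = 0.467) and 0.03 for 11 blood and immune cell markers (adjusted p = 1). In the Wnt and Notch list the median was above 0 and the camera test pointed down, in the apoptosis list the median was below 0 and the camera test pointed up, and the mean of the hepatocyte list was -0.01. In total 7 of the 27 lists passed, 5 higher and 2 lower. None of the 7 passed with an estimated correlation, which rests on 1 residual degree of freedom, nor with fry. The estimated correlation was 0.22 for cell cycle genes, 0.15 for heat shock proteins and 0.331 for ribosomal proteins, above the preset 0.01. It was negative for the other lists that passed.

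**Figure D4:**
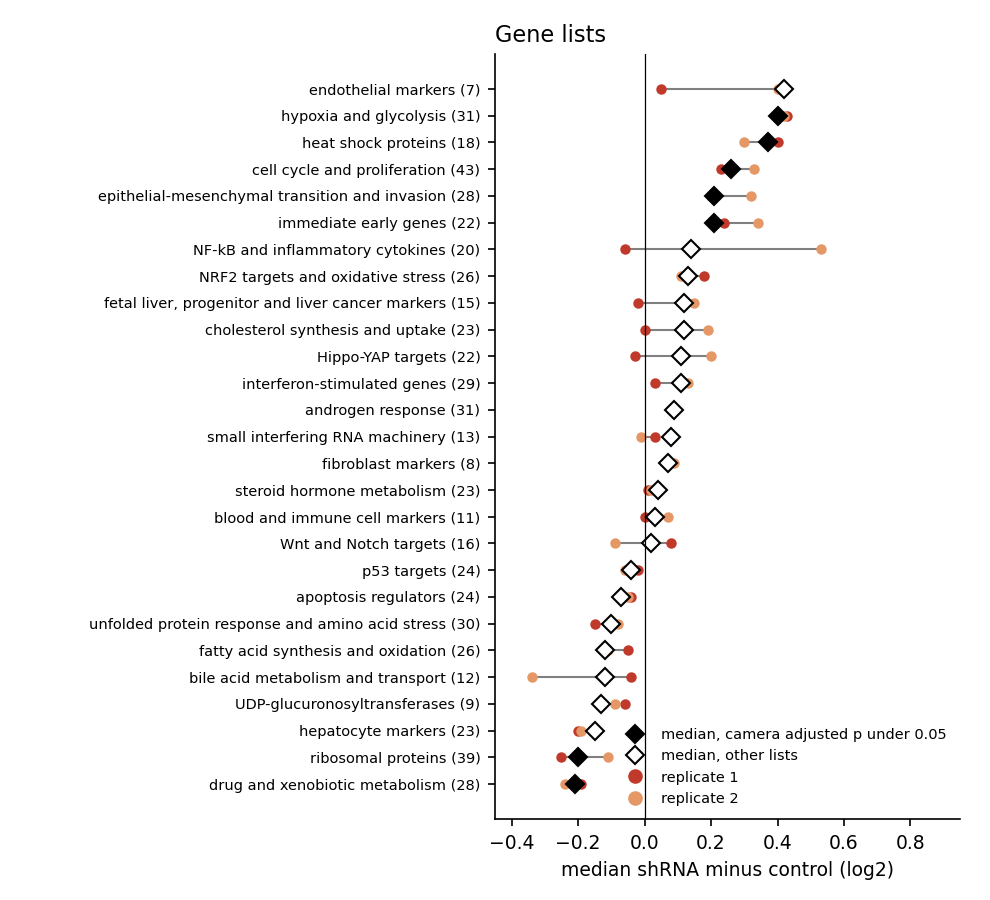
Median difference from the control array (x axis, log2) of the measured members of each of the 27 lists, with the number of members in brackets. Diamonds give the median of the members' mean differences, filled where the camera adjusted p was under 0.05, and circles the medians on shRNA replicates 1 and 2, which for the hypoxia and glycolysis list were 0.43 and 0.42.

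Across genes, the changes of the 2 shRNA arrays from the control ran together, with Pearson's r = 0.762 and Spearman's rho = 0.591 over 22107 features, which are not independent replicates. Both changes share the 1 control array, and unchanged arrays simulated with the spread between the shRNA arrays gave a mean r of 0.50 and a highest r of 0.521 in 100 draws. The covariance was 0.336 against 0.106 simulated. Over the 20022 features measured on all 3 arrays (each gene by its brightest such probe), r was 0.587 against a simulated mean of 0.50, and the covariance was 0.102 against 0.0722. The simulation did not repeat the filter on dim probes. That filter kept 695 features bright on the control alone and 676 bright on both shRNA arrays but not the control. The 2 changes of such features tend to share a sign, so part of the excess may come from the filter. Without a filter r was 0.533, with no simulation beside it. With 1 control array the controls could not be split, so part of the excess may also come from that array.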

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

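Cyclic loess normalization and the restriction to rows 193 to 384 of the array were chosen after seeing the data. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Leaving out a shRNA array leaves no residual degree of freedom, so no calls of genes or lists and no correlation could be made there. UGT2B15 stayed below control and short of the threshold in every setting that tested it, from -3.18 to -0.98 (normexp, where dim signals are drawn together by the offset), with adjusted p from 0.0591 to 0.363, and at -3.90 and -2.46 without one shRNA array.

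Of features called, 303 in the main setting, normexp gave 139 (41 higher and 98 lower, 69 shared with the 303), no filter on dim probes 774 among 43400 tested, an intensity trend in eBayes 48 (10 higher and 38 lower, 38 shared), and features with a symbol alone 114. Only features measured on all 3 arrays gave 0 with limma (1504 at an unadjusted p under 0.05), and rows 193 to 384 gave 0 (1072). The other settings gave 234 to 412. For features at least 2-fold from control on both shRNA arrays, 910 in the main setting, the counts were 141 with normexp, 245 measured on all 3 arrays, 2108 without a filter, 502 at a log2 difference of 1.5, 260 in rows 193 to 384 (180 higher and 80 lower, against 292 and 618), and 1526 to 1673 with 1 shRNA array left out. The shift from lower to higher in those rows goes with fewer control-only spots there. Of lists called, 7 in the main setting, no filter gave 4, robust eBayes 2, and an estimated correlation and fry 0 each, and other settings gave 6 to 10. The list counts with robust eBayes and with the trend also rest on another form of camera, run on the t values of the fit. The correlation of the changes, 0.762, was 0.639 with normexp, 0.587 over features measured on all 3 arrays, 0.533 without a filter and 0.768 with the mean of a gene's probes. For normexp, the trend, robust eBayes and the filters, the cause was not tested.

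List medians that changed sign were those of steroid hormone metabolism with normexp (-0.01), with features measured on all 3 arrays (-0.01) and with the mean of probes (-0.03), blood and immune cell markers with normexp (-0.02), Wnt and Notch targets with quantile normalization (-0.02), the deposited table (-0.02) and rows 193 to 384 (-0.01), fetal liver markers without a filter (-0.03) and fatty acid genes, from -0.12 to 0.15 in rows 193 to 384. The cause was not tested. The hypoxia and glycolysis list and the cell cycle list were called in 12 of 14 settings each, all but the estimated correlation and fry. Among genes, HSD11B1 turned to -0.01 with normexp, ACTB to -0.05 and SLC14A1 to 0.02 with the mean of probes, VEGFA, at 0.01, to -0.02 with quantile normalization, the deposited table and cyclic loess, and ACTB to -0.18 in rows 193 to 384, where another probe stood for it. Of the 31 named genes called, 8 passed in every setting that tested them, all of them lower and bright on the control alone, and IL6 and TRIML2 passed in 9 of 11 and 9 of 10. The restrictions to features measured on all 3 arrays and to rows 193 to 384, which gave no call, left these 8 genes out. IL6 was not called under either and TRIML2 not in rows 193 to 384, so the shares do not compare like with like. Of the 11 higher genes dim on the control, 5 passed with quantile normalization, 5 with the deposited table, 7 with cyclic loess, 1 with the trend and 1 with normexp, where ARG1 stood at 0.53 and NOTCH4 at 0.49. NOTCH4 and GALNT16 passed in 4 of 10 settings, CLDN22 and TENT5C in 4 of 9, ARG1 in 5 of 10, UCN2 in 5 of 9, LINC01349 in 6 of 10 and CRIM1 in 3 of 9. Of 78 named genes not called, 22 passed in at least 1 setting. Outside the 7 called lists, the NF-kB list passed in 5 of 14 settings, the bile acid list in 3 and the NRF2 list in 1. Signal over background limits most calls, since 24 of the 27 higher and 273 of the 276 lower features were dim on 1 side of the comparison.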

Other observations

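Gene lists for gastric and intestinal epithelium, epithelial junctions, alcohol and aldehyde dehydrogenases, glycolytic enzymes and other hypoxia-induced genes were written after the results were seen, and so were the tests of array position and bright neighbours. Genes of gastric and intestinal epithelium, from a list without the genes whose values had been read before, were lower on the shRNA arrays. Of 28 measured members, 19 were lower and 3 higher on both arrays, with a median log2 difference of -0.42 (limma camera adjusted p = 3e-04 over 5 lists, and adjusted p = 0.247 with an estimated correlation). The trefoil peptide TFF1 stood at -1.06, the gastric mucin MUC5AC at -1.15 and the tetraspanin TSPAN8 at -1.01. The intestinal lectin LGALS4 stood at -0.97 and the intestinal transcription factor CDX2 at -0.89, while GATA4 stood at 0.73. Over the alternatives MUC5AC ranged from -1.41 to -0.52 and GATA4 from 0.12 to 0.76. With shRNA replicate 1 and then replicate 2 set against the other arrays, the median of the list was 0.10 and 0.21. The hypothesis that transcripts of gastric and intestinal epithelium are lower in these cells stays open. The median of -0.42 lay outside the range of 1000 random lists (-0.19 to 0.29) but rests on 1 control array. Other lists also lay outside their range, among them hypoxia and glycolysis (0.40 against -0.18 to 0.17). Ribosomal proteins did too (-0.20 against -0.19 to 0.10), though their call ended with quantile normalization. Random lists cannot account for genes of a list that move together. Junction and surface genes of epithelia had a median of -0.09 (camera adjusted p = 0.285), with CLDN1, a claudin, at -1.20. CLDN1 ranged from -1.21 to -0.48 over the alternatives. Alcohol and aldehyde dehydrogenases had a median of -0.09 (camera adjusted p = 0.237).

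Within the fixed hypoxia and glycolysis list, the 15 glycolytic enzymes had a median of 0.40, with 14 higher on both arrays. All 15 are members of that list, so they add no evidence to it. Of 19 hypoxia-induced genes outside glycolysis, 9 are also on that list, among them the carbonic anhydrase CA9 at 0.88 and the growth factor gene VEGFA at 0.01. The other 10, among them ERO1A, an oxidase of protein folding, at 1.05, had a median of 0.51, with 8 higher and 0 lower on both arrays. They were chosen after the list was seen to rise. The chemokine genes CXCL1 and CXCL2 differed between the shRNA arrays. CXCL1 differed from control by -0.08 on replicate 1 and by 2.49 on replicate 2, and CXCL2 by -0.01 and 1.26. Chemokines were not tested as a list of their own. With replicate 2 set against the other 2 arrays, the NF-kB list had a median of -0.67 (replicate 1 and control minus replicate 2). It was 0.14 for the shRNA arrays minus control. The -0.67 lay further from 0 than the 0.40 of the hypoxia and glycolysis list in the real grouping. So 1 array set apart can move a list that far without being the control. With 1 control array, camera cannot tell an effect of the shRNA from a difference of that array.

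For the features lower on both shRNA arrays and bright on the control alone, local bright areas on the control array are a candidate explanation: 74.7% of the 273 called spots had another control-only spot among their 6 nearest, against a mean of 10.2% and a highest value of 17.6% in 1000 random draws from the same rows, 1 to 192 or 193 to 384. Such grouping was not particular to the control: of all spots bright on 1 array alone, 44.5% on the control and 35.0% and 34.1% on shRNA replicates 1 and 2 had such a neighbour. Of the 273, 95.6% lay in rows 1 to 192, against 50% of all spots that are not controls. Lower transcripts of these genes give no reason for such placing, so these values argue against them as the explanation of the whole set. For single genes they stay open. Of 128 other probes of 93 of these genes, 1 (0.781%, 95% interval 0.0198 to 4.28, exact binomial) was likewise lower, but 119 were dim on every array and cannot show a fall, so the bound set for this test decides nothing. There are too few splits of the 3 arrays for a share under 0.05; the real grouping gave 273 such features and the highest other 121.

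For the hypoxia and glycolysis list, a signal-dependent difference between the arrays was excluded as the whole cause, since the median stayed at 0.40 after cyclic loess normalization. Local bright areas that cover several spots were tested on the spots near those of the list. Among the 6 nearest to each, 73 were measured on all 3 arrays. Their median log2 difference was 0.00 (95% bootstrap interval -0.09 to 0.11), which argues against such areas as the whole cause. Neighbours dim on any array were left out, so the test could not see bright areas among dim spots. There are too few splits for a share under 0.05; the real median was 0.40 and the highest other 0.30 in absolute value. A difference in culture of the 1 control dish, such as its density, was not tested.

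For UGT2B15, bleeding of its brightest neighbouring spot by the same share on every array was excluded as the source of the control signal. The UGT2B15 signal on shRNA replicate 1 was 21.4% of that on the control while the neighbouring spot was 131% of its control signal. Bleeding on the control array alone was not tested. The spot lies in row 378, far from rows 1 to 192, and none of its 6 nearest spots was bright on the control alone. A single brightened spot on the control array could give the same value as the 21.4% seen here and was not tested.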
